A study of Homo sapiens with 24 samples.

How the data were processed

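The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments), made by the authors. With this scaling, a rise or fall of a gene is relative to the other genes of a library. A change in total RNA per cell would not show. The column headers do not name the unit. It was taken from the fractional values, from their sums, and from the layout that Cuffdiff writes. Per the labels, RNA was extracted with the Qiagen RNAEasy kit, and libraries were made with the TruSeq Stranded mRNA kit from polyadenylated RNA. The processing notes name bcl2fastq 2.17.1.14, TopHat2 2.1.1, Cuffdiff 2.2.1 and the genome build hg19, without the role or the order of each tool. There are 4 tables, 1 per cell line and folic acid condition, each with the same 23595 genes. Whether the 4 tables shared 1 normalization is not stated. Read counts were not analysed here, so the depth of each library is unknown and no counting interval or floor was computed.

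The 24 libraries fall into 8 groups of 3: the lines IMS-M2 and U937, each with folic acid (+FA) or without it (-FA), and each treated with DMSO or OTX. In the U937 -FA table the columns are numbered from 0 and the labels from 1. Those 6 libraries were therefore assigned to their groups only, and are called column 0, 1 and 2. The labels do not say that the 3 libraries of a group came from separate cultures, so every p-value measures only the spread between samples.

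Gene tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1). The pseudocount of 1 FPKM understates the change of genes with low values. A group-means model was fitted to the 12 libraries of a line, or to all 24 libraries for the difference between lines, with eBayes and an intensity trend. Genes with a mean of at least 1 FPKM in at least 1 group were tested. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, and a second count took calls with a log2 change of at least 1 in either direction. The contrasts were OTX minus DMSO in each line and folic acid condition, the -FA change minus the +FA change in each line, and the U937 change minus the IMS-M2 change with folic acid. Levels without and with folic acid in DMSO come from separate tables, so they are given as levels without a test.

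There were 24 gene lists, tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and again after rescaling. Adjusted p-values of lists are over the lists of a contrast. The lists were BET inhibitor response reported as raised, BET inhibitor response reported as lowered, MYC targets, folate and methionine cycle, serine synthesis and ATF4 response, p53 targets, DNA replication and S phase, mitosis and G2/M phase, monocyte and macrophage markers, granulocyte and myeloblast granule markers, leukaemic stem cell and HOX programme, and DNA and histone methylation enzymes. The others were BET proteins and transcription elongation, cholesterol synthesis, BCL2 family, interferon response, inflammatory cytokines and NF-kB targets, immediate early genes, heat shock response, erythroid and megakaryocyte markers, lymphoid markers, stromal and epithelial markers, histone genes, and cytosolic ribosomal proteins. The lists, the main tests, the rule for naming genes and all but 3 alternatives were set before the data were examined. Removing the length trend, leaving out small RNA symbols, and camera without each library came after, as did the tests of explanations other than the regroupings.

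Some genes that these rules would name are not reported here. The genes MYC, HEXIM1, SERPINI1, BCL2, CDK6, BRD2 and CD180 were named in every contrast whatever their result. Each contrast then named the 6 highest and 6 lowest log2 changes among called genes. In the OTX contrasts such a gene also needed a mean of at least 5 FPKM in a group. Its 3 OTX libraries also had to lie on one side of the 3 DMSO libraries, which chance gives in 10% of genes. The contrasts of differences had neither condition, so their leading genes can be low. From each list described, up to 4 members per direction with the smallest p were eligible. For the levels in DMSO, MYC and the 4 folate and methionine cycle genes with the largest differences were named. Symbols with more than 1 row and unnamed or readthrough loci were left out of the ranking, as were XIST, TSIX and Y-linked genes everywhere. A total of 6388 genes share a locus in the tables with another gene, and their positions cover the whole locus.

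The procedure was tested on simulated data with the spread of these libraries and known changes. In each contrast 100 genes were changed by a log2 of 1 and 100 by 0.5. A log2 change of 1 was called in 98% of changed genes for each OTX contrast in IMS-M2, in 93% and 94% of those in U937 with and without folic acid, in 91% and 76% for the folic acid difference in IMS-M2 and U937, and in 84% for the line difference. For a log2 change of 0.5 these shares were 62% and 69% in IMS-M2, 58% and 56% in U937, 32% and 13% for the folic acid differences, and 30% for the line difference. Between 4 and 12 unchanged genes were called per contrast, and 0 unchanged lists. Noise was drawn independently for each gene and no library deviated as a whole, so these low counts were largely given by the setting. They cannot show how often correlated genes or a deviating library give false calls. In the real data the estimated correlation of lymphoid markers in IMS-M2 was 0.454. Changed genes were drawn only from genes well above the filter of 1 FPKM, so the shares may overstate recovery of low genes. Far more genes were called in the real OTX contrasts (56.1% to 63.2%). The adjusted p depends on that share, so the simulated recovery need not hold for them.

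Alternatives were pseudocounts of 0.1 and 0.01 FPKM, no filter on low values, a mean of at least 5 FPKM, median-of-ratios rescaling, quantile normalization, a replicate block in the tables whose numbers match the labels, no intensity trend, array weights, a fit of the 6 libraries of a table alone, and leaving out each library in turn. Removing each library's transcript length trend and leaving out small RNA symbols were added after the data were seen. Transcript lengths came from GENCODE v29 by symbol, for 21189 of 23595 genes (89.8%). Groups of 3 libraries were too small for a test of single deviating values.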

Results

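Polyadenylated RNA of 2 human acute myeloid leukaemia cell lines, IMS-M2 and the monocytic line U937, was sequenced in 24 libraries. Each line was grown with folic acid (+FA) or without it (-FA) and treated with OTX or with its solvent DMSO, giving 8 groups of 3 libraries. OTX is taken from what is known of the study to be birabresib, an inhibitor of the BET bromodomain proteins, since the labels give only the abbreviation. They give no dose or duration of the OTX treatment. The title of the series asks how folic acid deprivation changes the transcriptional effect of OTX. The values are FPKM for 23595 genes, and the sequencing depth is unknown. FPKM sums per library ran from 522659 to 644841, and 10418 to 10894 genes reached 1 FPKM. Within groups, the Pearson correlation of log2 values across genes ran from 0.972 to 0.993, where genes are not independent replicates.

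The first comparison asked what OTX did to IMS-M2 cells with folic acid. HEXIM1, an inhibitor of the elongation factor P-TEFb and a common readout of BET inhibition, rose from 6.77 ± 1.04 to 37.2 ± 1.74 FPKM (mean ± SD, n = 3 per group). MYC, a transcription factor that drives growth, fell only from 197 ± 11.2 to 142 ± 0.748 FPKM, a log2 change of -0.47 ± 0.066 (SE). IGLL1, a surrogate light chain of early B cells, fell from 188.5 ± 40.2 to 1.44 ± 0.106 FPKM, and SLC2A5, a fructose transporter, fell from 68.5 ± 6.58 to 1.24 ± 0.165 FPKM. IER3, a stress response gene, rose from 2.50 ± 0.136 to 40.6 ± 1.10 FPKM, and TXNIP, an inhibitor of thioredoxin and glucose uptake, rose from 17.5 ± 1.88 to 132 ± 1.55 FPKM. The chemokine CCL1 stood at 34.7 ± 2.2 FPKM in DMSO and was listed at 0 in all 3 OTX libraries.

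SLC38A5, an amino acid transporter, also fell with folic acid in IMS-M2 (log2 -4.77). The histone gene HIST1H2AC rose by 2.80 on the log2 scale. Small nucleolar RNA genes also ranked high, but their values scattered. SNORA44 went from 10.3 ± 17.9 to 126 ± 60.1 FPKM, SNORA33 went from 2.59 ± 4.48 to 54.1 ± 7.61 FPKM, and both share a locus with a host gene. SNORA81 was listed at 0 in DMSO and SNORA40 was listed at 0 under OTX. SERPINI1, a serpin used as a marker of BET inhibition, rose from 0.467 ± 0.0407 to 2.11 ± 0.434 FPKM, and BRD2, itself a BET protein, rose by 0.82 on the log2 scale. BCL2, an inhibitor of cell death, rose by 0.29. BCL2 lost its call without DMSO replicate 3 (adjusted p = 0.0973) or OTX replicate 2 (0.0669). CDK6 (log2 0.08), a kinase of the cell cycle, did not pass the test, and CD180 lay below the filter at 0.0389 FPKM in DMSO. In limma, 7091 of 11223 genes changed, 3341 higher and 3750 lower. With a log2 change of at least 1 there were 1184, 303 higher and 881 lower. MYC had an adjusted p of 5.03e-05 and HEXIM1 7.38e-10, with all 3 OTX libraries on one side of the DMSO libraries for both.

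Without folic acid, the question was the same, and OTX again raised HEXIM1 in IMS-M2, from 9.15 ± 0.847 to 40.3 ± 1.06 FPKM (mean ± SD, n = 3 per group). MYC fell from 183 ± 2.94 to 119 ± 1.95 FPKM, a log2 change of -0.62. IGLL1 fell from 139.5 ± 11.4 to 0.637 ± 0.162 FPKM. NRXN2, a neuronal adhesion gene, fell from 51.0 ± 0.904 to 1.19 ± 0.222 FPKM, ANGPT1, a vascular growth factor, fell from 35.2 ± 5.18 to 0.646 ± 0.0835 FPKM, and the imprinted noncoding RNA H19 fell by 4.17 on the log2 scale. CCL1 stood at 24.2 ± 1.62 FPKM in DMSO and was again listed at 0 under OTX. IER3 rose by 3.36, HIST1H2AC by 2.93, HIST2H2BE by 2.82, HIST1H2BC by 2.73, HIST1H2BD by 2.61 and TXNIP by 2.56 on the log2 scale. SERPINI1 rose by 1.06 and BRD2 by 1.01, BCL2 fell by 0.36, and CDK6 (log2 0.07) did not pass the test. In limma, 6455 of 11223 genes changed, 3085 higher and 3370 lower, with 893 at a log2 change of at least 1 (199 higher and 694 lower). MYC had an adjusted p of 5.67e-06 and lay lower in all 3 OTX libraries.

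**Figure D1:**
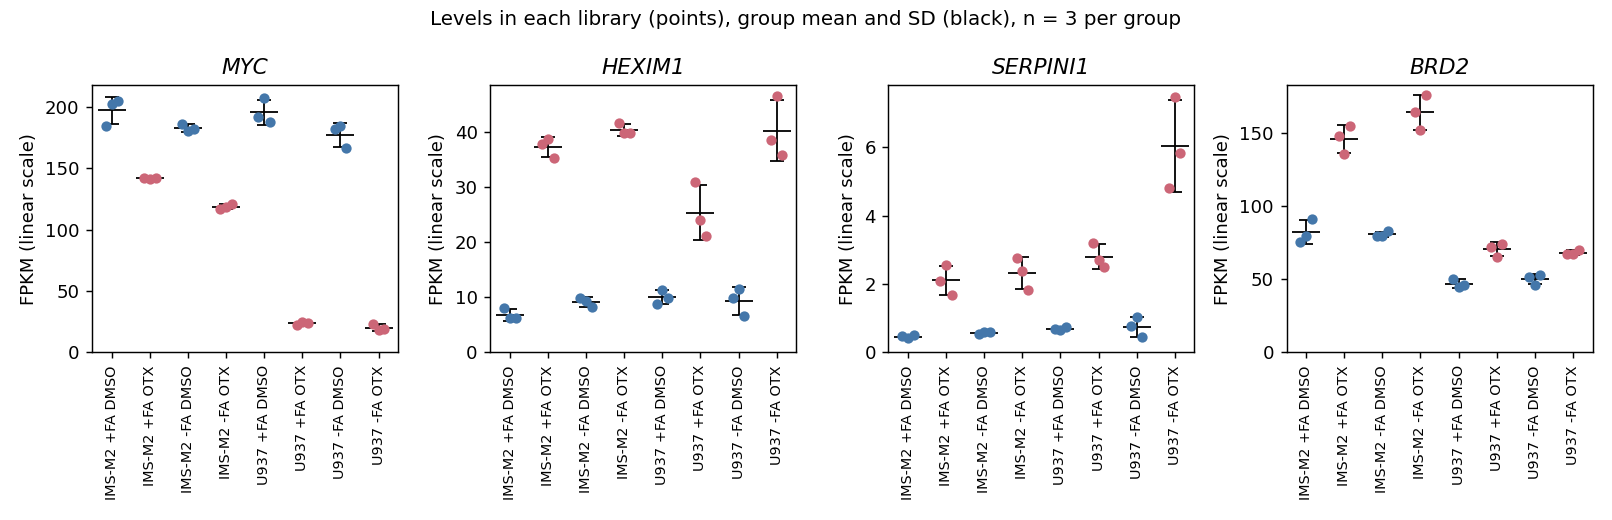
FPKM (linear scale) of MYC, HEXIM1, SERPINI1 and BRD2 in each of the 24 libraries, by group, with DMSO in blue, OTX in red and the group mean and SD in black (n = 3). MYC lay between 18.5 and 25.2 FPKM in the 6 U937 OTX libraries and between 117 and 142 FPKM in the 6 IMS-M2 OTX libraries.

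Histone gene transcripts in polyadenylated RNA rose in IMS-M2, with 32 of 39 measured genes (72 listed) higher and 0 lower with folic acid. Adjusted over the list alone 33 were higher, and the median log2 change was 0.92. Transcripts without a poly(A) tail were not sampled, so the change of total histone RNA is unknown. HIST1H3D rose by 1.71 and HIST1H2BK by 1.49. Without folic acid 26 were higher and 0 lower (28 adjusted over the list alone), with a median of 0.80. The camera adjusted p was 2.18e-08 with folic acid and 4.27e-08 without it. These 2 calls and those of MYC targets and of serine synthesis and ATF4 response genes in U937 with folic acid were the 4, of 42 list calls under OTX, that held with an estimated correlation. For histone genes that gave 0.0317 and 0.0353. Genes reported as raised by BET inhibitors rose in 9 of 10 cases in both conditions (median log2 1.76 and 1.86, with 9 adjusted over the list alone in each), with 1 member lower over the list alone in each. The camera adjusted p was 3.29e-05 with folic acid and 7.78e-06 without it. With an estimated correlation these were lost, at adjusted p = 0.0978 with an estimated correlation and 0.0739. This list holds HEXIM1, SERPINI1 and histone genes such as HIST1H2BK, HIST1H2AC and HIST2H2BE, which are also in the histone list. In both lines its rise and that of the histone list are therefore not separate evidence.

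Among genes reported as lowered by BET inhibitors, 8 of 11 fell and 1 rose in IMS-M2 with folic acid (8 and 1 adjusted over the list alone), with a median log2 change of -0.80. TYRO3, a receptor kinase, fell by 2.58, IL7R, a cytokine receptor, by 1.91 and CSF1R, a macrophage growth factor receptor, by 1.29. Camera gave an adjusted p of 0.00195 and an adjusted p = 0.0864 with an estimated correlation. Without folic acid 10 fell (10 adjusted over the list alone), with a median of -0.56 and an adjusted p of 0.000212, and an adjusted p = 0.0535 with an estimated correlation. MYC targets fell in 42 of 60 cases and rose in 5 with folic acid (42 and 5 adjusted over the list alone), with a median of -0.44. DUSP2, a phosphatase, fell by 1.42 and PPAN, a ribosome assembly factor, by 1.13, and ODC1, the first enzyme of polyamine synthesis, rose by 0.56. The adjusted p was 3.72e-05, and adjusted p = 0.124 with an estimated correlation. Without folic acid 47 fell and 2 rose (49 and 2 adjusted over the list alone), with a median of -0.49 and an adjusted p of 1.13e-07, and an adjusted p = 0.0739 with an estimated correlation.

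Monocyte and macrophage markers fell in IMS-M2 in 8 of 9 cases with folic acid (8 adjusted over the list alone; median log2 -1.15). The protease CTSS fell by 2.93 and lysozyme, LYZ, by 2.54. The camera adjusted p was 3.8e-05, and adjusted p = 0.0864 with an estimated correlation. Without folic acid 8 fell and 1 rose (8 and 1 adjusted over the list alone; median -0.95), with an adjusted p of 0.000428 and an adjusted p = 0.0739 with an estimated correlation. Granule markers fell in 2 of 3 cases with folic acid (3 adjusted over the list alone), among them the protease CTSG (log2 -3.58) and the peroxidase MPO (log2 -1.66). Camera put their adjusted p at 0.0193, and adjusted p = 0.124 with an estimated correlation. Without folic acid all 3 fell (3 adjusted over the list alone), at an adjusted p of 0.0149 and an adjusted p = 0.098 with an estimated correlation. All 6 lymphoid markers fell in both conditions (6 adjusted over the list alone), led by the kinase LCK (log2 -2.41 and -2.84) and the B cell receptor subunit CD79B (-2.66 and -2.56). In camera the adjusted p was 0.000165 and 0.00012, and adjusted p = 0.16 and 0.144 with an estimated correlation. All 4 stromal and epithelial markers fell in both (4 adjusted over the list alone), led by the adhesion genes PECAM1 (-2.24 and -2.19) and CDH5 (-1.81 and -1.59). Tested with camera, they had an adjusted p of 0.00969 and 0.00597, and adjusted p = 0.161 and 0.146 with an estimated correlation.

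Inflammatory genes went both ways in IMS-M2. With folic acid 12 of 19 rose and 5 fell (12 and 5 adjusted over the list alone; median log2 0.69). TNF, an inflammatory cytokine, rose by 1.46 and the NF-kB inhibitor NFKBIA by 1.07, while TNFAIP2 fell by 2.31 and the neutrophil chemokine IL8 by 1.36. The list had an adjusted p of 0.0329, and adjusted p = 0.305 with an estimated correlation. Without folic acid 13 rose and 4 fell (13 and 4 adjusted over the list alone; median 0.68), with an adjusted p of 0.0107 and an adjusted p = 0.234 with an estimated correlation. Mitosis genes rose in 20 of 30 cases and fell in 2 with folic acid (20 and 2 adjusted over the list alone; median 0.45), led by ANLN, a scaffold of cell division, at 0.80 and the motor protein KIF11 at 0.96. For this list camera gave an adjusted p of 0.000384, and adjusted p = 0.298 with an estimated correlation. Without folic acid the mitosis list was not called (7 rose, 2 fell, 5 and 2 adjusted over the list alone, median 0.09, adjusted p = 0.25). Among p53 targets 12 of 21 rose and 5 fell with folic acid (12 and 5 adjusted over the list alone; median 0.36). BTG2, which slows the cell cycle, rose by 1.90 and the death receptor FAS fell by 1.05. Camera put their adjusted p at 0.0471, and adjusted p = 0.161 with an estimated correlation, 0.0611 after rescaling or 0.06 with the length trend removed. Without folic acid p53 targets had an adjusted p of 0.194.

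Serine synthesis and ATF4 response genes rose in IMS-M2 without folic acid in 14 of 25 cases and fell in 3 (14 and 3 adjusted over the list alone; median log2 0.32). Their adjusted p was 0.00747, and adjusted p = 0.234 with an estimated correlation. With folic acid 6 rose and 13 fell (6 and 14 adjusted over the list alone; median -0.26, adjusted p = 0.206). BET proteins and transcription elongation genes rose in 8 of 19 cases and fell in 1 without folic acid (8 and 1 adjusted over the list alone; median 0.19), led by the elongation factors ELL2 at 1.35 and AFF1 at 1.34. Tested with camera, they had an adjusted p of 0.0364, and adjusted p = 0.283 with an estimated correlation or 0.06 with the length trend removed. With folic acid the adjusted p was 0.142. In IMS-M2 the remaining lists were not called with and without folic acid, in that order. The medians were -0.08 and 0.01 for the folate and methionine cycle (adjusted p = 0.4 and 0.641), 0.02 and -0.13 for DNA replication and S phase (0.366 and 0.537), 0.28 and 0.07 for the HOX programme (0.228 and 0.682), and -0.10 and -0.06 for methylation enzymes (0.46 and 0.735). They were 0.01 and 0.22 for cholesterol synthesis (0.613 and 0.0689), 0.04 and -0.03 for the BCL2 family (0.681 and 0.855), 0.04 and 0.11 for interferon response (0.613 and 0.551), and 0.40 and 0.43 for immediate early genes (0.0982 and 0.101). They were 0.06 and -0.12 for heat shock response (0.689 and 0.304), -0.53 and -0.53 for erythroid and megakaryocyte markers (0.0982 and 0.061), and -0.13 and -0.10 for ribosomal proteins (0.689 and 0.499). Median, mean and test differed in sign for interferon response in both conditions, for the BCL2 family in both, and without folic acid for the folate and methionine cycle and the HOX programme.

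The next comparison asked what OTX did to U937 cells. MYC fell from 196 ± 10.1 to 23.96 ± 1.27 FPKM with folic acid and from 177 ± 9.74 to 20.2 ± 2.60 FPKM without it (mean ± SD, n = 3 per group). The log2 changes were -2.98 ± 0.094 and -3.08 ± 0.094 (SE). The cell cycle inhibitor CDKN1A rose from 2.98 ± 0.217 to 39.2 ± 5.63 FPKM with folic acid and from 3.97 ± 0.527 to 59.8 ± 7.72 FPKM without it. MS4A3, a marker of granulocyte and monocyte progenitors, fell from 68.5 ± 4.05 to 5.33 ± 0.967 FPKM and from 54.9 ± 1.47 to 3.12 ± 0.149 FPKM. CYBB, a subunit of the phagocyte oxidase, fell from 20.02 ± 2.35 to 1.52 ± 0.0947 FPKM and from 41.5 ± 2.07 to 2.63 ± 0.516 FPKM. HEXIM1 rose from 10.03 ± 1.24 to 25.3 ± 4.997 FPKM and from 9.30 ± 2.49 to 40.2 ± 5.56 FPKM.

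With folic acid, CD82, a membrane organiser, rose by 2.86 on the log2 scale in U937, IRF7, an interferon regulator, by 2.67, ID2, an inhibitor of differentiation factors, by 2.51, the lipid transporter ABCA7 by 2.25 and the activation marker CD69 by 2.24. PLAC8 fell by 3.46, ACTL8, an actin-like gene, by 3.34 and FCER2, an IgE receptor, by 3.04. Without folic acid the noncoding RNA NEAT1 rose by 2.69, IER3 by 2.58, ID2 by 2.52 and FTL, a ferritin subunit, by 2.51, and TARP, a T cell receptor transcript, fell by 3.13. The small RNA genes SNORA10 and SNORA24 were listed at 0 under OTX without folic acid, and SNORA24 was no longer called without DMSO column 1 (adjusted p = 0.0678). SERPINI1 rose by 1.16 with and 2.0 without folic acid, and BRD2 by 0.58 and 0.44. CD180, a receptor of B cells and monocytes, fell from 1.89 ± 0.291 to 0.156 ± 0.0261 FPKM and from 4.90 ± 0.352 to 0.376 ± 0.108 FPKM. CDK6 fell by 0.70 without folic acid (log2 -0.26 with it, not past the test), and BCL2 passed in neither (log2 -0.12 and -0.18).

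In limma, 6281 of 11194 genes changed in U937 with folic acid, 3258 higher and 3023 lower, with 891 at a log2 change of at least 1 (329 higher and 562 lower). Without folic acid 6690 changed, 3139 higher and 3551 lower, with 1071 at a log2 change of at least 1 (378 higher and 693 lower). MYC had an adjusted p of 5.01e-09 with and 2.77e-09 without folic acid and lay lower in all 3 OTX libraries of each table. HEXIM1 had an adjusted p of 0.000169 and 4.04e-06.

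MYC targets fell in U937 in 52 of 59 cases and rose in 2 with folic acid (53 and 2 adjusted over the list alone; median log2 -0.97). WDR74, a ribosome assembly factor, fell by 1.71, NOLC1, a nucleolar chaperone, by 1.40 and IPO4, a nuclear import receptor, by 1.82. The list had an adjusted p of 1.83e-16, and it held at 0.043 with an estimated correlation. Without folic acid 54 fell and 0 rose (54 and 1 adjusted over the list alone; median -1.0), with an adjusted p of 5.27e-16 and an adjusted p = 0.0548 with an estimated correlation. Serine synthesis and ATF4 response genes fell in 16 of 24 cases and rose in 2 with folic acid (17 and 2 adjusted over the list alone; median -0.64). ATF4, the regulator of the amino acid response, fell by 1.44, its target TRIB3 by 1.52 and the amino acid transporter SLC7A5 by 1.58, and DDIT4 rose by 0.95. For this list camera gave an adjusted p of 6.65e-05, and it held at 0.043 with an estimated correlation. Without folic acid 16 fell and 1 rose (16 and 1 adjusted over the list alone; median -0.59), with an adjusted p of 0.000217 and an adjusted p = 0.0548 with an estimated correlation.

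Ribosomal protein genes fell in U937 in 40 of 75 cases and rose in 1 with folic acid (40 and 1 adjusted over the list alone; median log2 -0.38). RPL13A fell by 0.78 and RPL29 by 0.83. Camera put their adjusted p at 3.27e-05, and adjusted p = 0.195 with an estimated correlation. Without folic acid 53 fell and 3 rose (55 and 3 adjusted over the list alone; median -0.60), with an adjusted p of 4.81e-06 and an adjusted p = 0.137 with an estimated correlation. Folate and methionine cycle genes fell in 12 of 24 cases and rose in 3 without folic acid (12 and 3 adjusted over the list alone; median -0.45). The mitochondrial folate enzyme MTHFD1L fell by 2.32, the phospholipid methyltransferase PEMT by 1.92, CBS, which commits homocysteine to cysteine, by 2.08 and the purine synthesis enzyme GART by 1.15. SHMT1, a serine hydroxymethyltransferase, rose by 0.43. In camera the adjusted p was 0.00591, and adjusted p = 0.172 with an estimated correlation. With folic acid 13 fell and 6 rose (13 and 6 adjusted over the list alone; median -0.39), and the list was not called (adjusted p = 0.0583).

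Genes reported as raised by BET inhibitors rose in U937 in 7 of 11 cases with folic acid and 8 without it, with 1 lower in each (the same counts adjusted over the list alone; medians log2 0.87 and 1.63). HIST1H2BK rose by 1.5 and 1.71, while KLF9, a transcription factor, fell by 0.43 and 0.27. Tested with camera, they had an adjusted p of 0.0497 and 0.000797, and adjusted p = 0.362 and 0.169 with an estimated correlation. Those reported as lowered fell in 6 and 7 of 10 cases, with 1 higher in each (the same adjusted over the list alone; medians -0.46 and -0.97). The cyclin CCND2 fell by 1.61 and 1.51, and E2F2, a cell cycle factor, rose by 0.42 and 0.29. The adjusted p was 0.00877 and 0.00103, and adjusted p = 0.114 and 0.0548 with an estimated correlation. Histone genes rose in 11 of 22 cases in both, with 1 lower with folic acid and 0 without it (the same adjusted over the list alone; medians 0.47 and 0.65). For this list camera gave an adjusted p of 0.00552 and 0.00126, and adjusted p = 0.195 and 0.137 with an estimated correlation. Immediate early genes rose in 10 and 12 of 15 cases, with 1 lower in each (11 and 2, then 12 and 1, adjusted over the list alone; medians 0.84 and 1.05). DUSP6, a phosphatase of growth signalling, rose by 1.91 and 1.98 and the transcription factor EGR1 by 1.44 and 1.94. Camera put their adjusted p at 0.000707 and 4.23e-05, and adjusted p = 0.114 and 0.0548 with an estimated correlation.

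Mitosis genes rose in U937 in 18 and 20 of 30 cases, with 0 lower (the same adjusted over the list alone; medians log2 0.29 and 0.48), with ANLN at 0.74 and 0.76. In camera the adjusted p was 0.00225 and 1.49e-05, and adjusted p = 0.316 and 0.145 with an estimated correlation. Without folic acid 14 of 21 interferon response genes rose and 4 fell (14 and 4 adjusted over the list alone; median 0.81). IFIT2, an antiviral RNA binding protein, rose by 1.72 and IRF7 by 2.74, while IFITM1, an inhibitor of viral entry, fell by 1.61. Tested with camera, they had an adjusted p of 0.00221, and adjusted p = 0.145 with an estimated correlation. Among HOX programme genes 7 of 11 rose and 2 fell without folic acid (7 and 2 adjusted over the list alone; median 0.79), with HOXA10 at 2.01, HOXA9 at 1.93 and the repressor GFI1 at -0.45. The list had an adjusted p of 0.0328, and adjusted p = 0.137 with an estimated correlation. Among p53 targets 8 of 16 rose and 2 fell without folic acid (8 and 2 adjusted over the list alone; median 0.24), with RRM2B, a ribonucleotide reductase subunit, at 1.46 and the nuclease AEN at -1.53. For this list camera gave an adjusted p of 0.0316, and adjusted p = 0.137 with an estimated correlation. With folic acid these 3 lists were not called, at an adjusted p of 0.0756 for interferon response, 0.0875 for the HOX programme and 0.0723 for p53 targets.

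In U937 the remaining lists were not called, with and without folic acid in that order. The medians were 0.14 and -0.26 for DNA replication and S phase (adjusted p = 0.0756 and 0.196), -0.39 and -0.33 for monocyte markers (0.116 and 0.249), -1.12 and -0.62 for granule markers (0.066 and 0.318), and 0.05 and -0.22 for methylation enzymes (0.758 and 0.249). They were 0.14 and 0.04 for BET proteins and elongation (0.0756 and 0.461), 0.09 and -0.06 for cholesterol synthesis (0.627 and 0.802), -0.04 and 0.18 for the BCL2 family (0.758 and 0.547), and -0.13 and -0.41 for inflammatory genes (0.599 and 0.318). They were 0.00 and -0.07 for heat shock response (0.745 and 0.798), -0.22 and -1.14 for erythroid markers (0.319 and 0.196), and -0.57 and -0.43 for lymphoid markers (0.0686 and 0.196). No stromal list could be tested in U937. Median, mean and test differed in sign for the BCL2 family with folic acid, for cholesterol synthesis without it and for heat shock response in both.

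**Figure D2:**
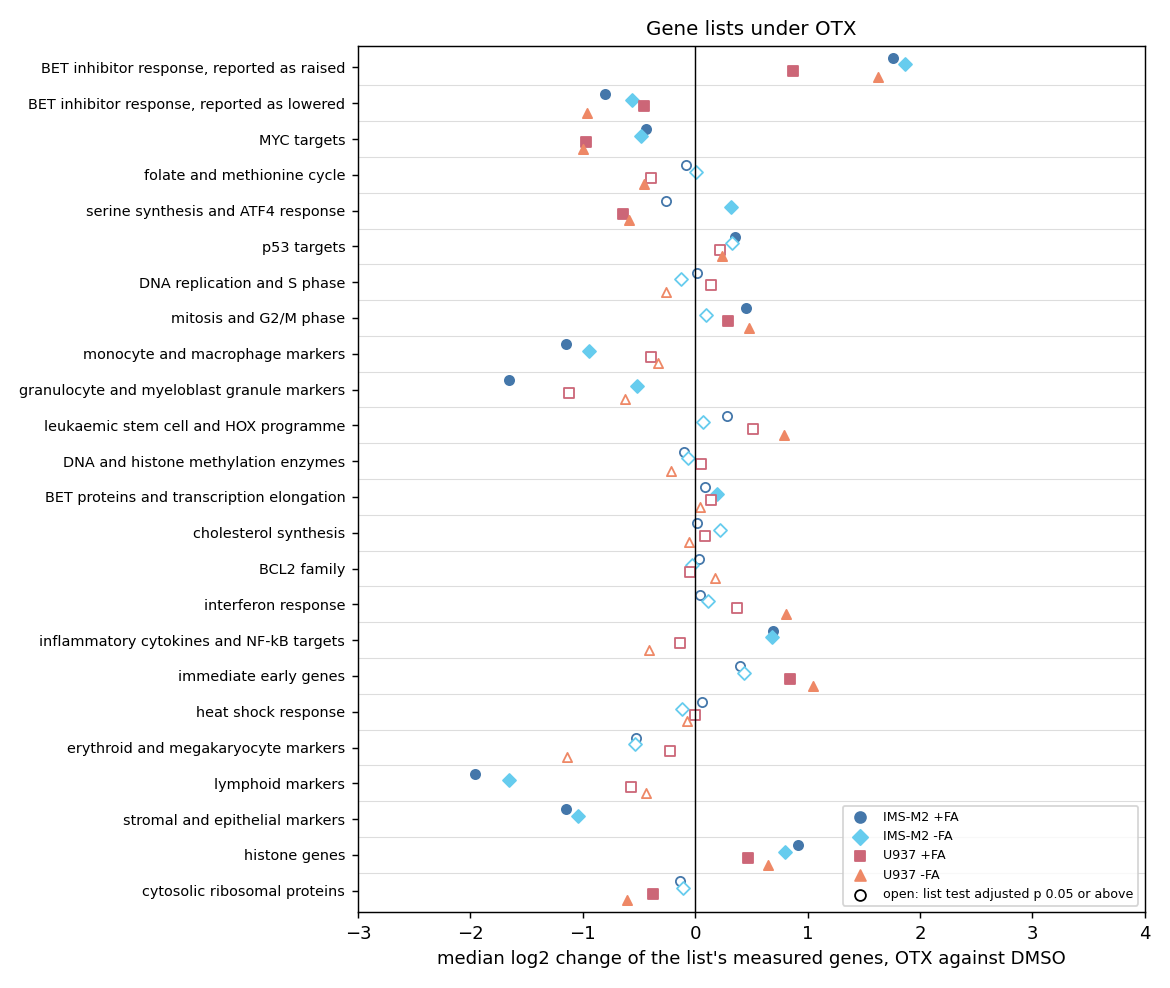
Median log2 change (OTX against DMSO, x axis) of the measured genes of each list (y axis), with circles and diamonds for IMS-M2 and squares and triangles for U937, and open symbols for an adjusted p of 0.05 or above. MYC targets lay at -0.44 and -0.49 in IMS-M2 and at -0.97 and -1.0 in U937.

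The next comparison asked where the 2 lines differed under OTX with folic acid, as the U937 change minus the IMS-M2 change. MYC fell further in U937, by 2.51 ± 0.11 on the log2 scale (SE, n = 3 libraries per group), while HEXIM1 rose less there (difference -1.06 ± 0.22). Several large differences lay in genes that 1 line hardly expressed. They were -3.42 for MS4A3, at a mean of 0.061 FPKM in IMS-M2 DMSO, and 5.15 for CCL1, 4.30 for the adhesion receptor SELP and 4.13 for ANGPT1, all listed at 0 in U937 DMSO. SLC38A5 differed by 4.56, at 0.252 FPKM in U937 DMSO, and IGLL1 by 4.76. CD53, a leukocyte membrane protein, differed by 4.20, with means of 39.8 and 5.30 FPKM in DMSO and OTX in IMS-M2 and 15.2 and 45.2 FPKM in U937. IGLL1 was low in U937 and lost its call with a pseudocount of 0.01 FPKM (log2 1.33, adjusted p = 0.2). The noncoding RNA genes SNORA44 (-6.93), SNORA33 (-4.73), SNORA6 (-3.61), SNORA81 (-3.43) and BCYRN1 (-3.74) had scattered values and share loci. SNORA33 lost its call without any of the 3 IMS-M2 OTX libraries (adjusted p from 0.0563 to 0.0619) or of the 6 U937 libraries (0.0526 to 0.0614), or without IMS-M2 DMSO replicate 1 or 2 (0.0767 and 0.0843). SNORA6 kept its call only without IMS-M2 OTX replicate 1 or U937 DMSO replicate 1 or 3 (0.0543 to 0.135 otherwise). SNORA81 lost its call without U937 DMSO replicate 1 (0.0565), and BCYRN1 without IMS-M2 DMSO replicate 3 (0.0587) or U937 DMSO replicate 2 (0.0507). CD180, below the filter in IMS-M2, differed by -1.27. BCL2 differed by -0.42, having risen in IMS-M2 (0.29) and not passed in U937 (-0.12, adjusted p = 0.236). SERPINI1 (0.09), BRD2 (-0.25) and CDK6 (-0.34) did not pass. BRD2 passed without IMS-M2 DMSO replicate 3 (-0.32, 0.0254) or IMS-M2 OTX replicate 2 (-0.30, 0.0462). In limma, 6175 of 12197 genes differed, 3378 higher and 2797 lower, and 1381 by a log2 of at least 1 (879 higher and 502 lower). MYC had an adjusted p of 2.09e-13 and HEXIM1 0.000505.

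Lists also differed between the lines. Here and in the next paragraph, higher and lower refer to the OTX change in U937 against that in IMS-M2, not to levels. MYC targets were lower in U937 in 42 of 60 cases and higher in 3 (42 and 3 adjusted over the list alone; median log2 difference -0.56), among them NOLC1 (-1.10) and the nucleolar protein NPM1 (-1.03) against the nucleoside transporter SLC29A2 (1.19), which lay below the filter in U937. The adjusted p was 2.39e-08, and adjusted p = 0.0886 with an estimated correlation. Histone genes were lower in 16 of 41 cases (11 adjusted over the list alone; median -0.48), led by HIST2H2BE (-1.73) and HIST1H1B (-1.25), the latter below the filter in U937. In camera the adjusted p was 0.00187, and adjusted p = 0.0886 with an estimated correlation. Ribosomal protein genes were lower in 31 of 75 cases and higher in 2 (31 and 2 adjusted over the list alone; median -0.26), with RPL4 at -0.69 and RPL12 at -0.75. Tested with camera, they had an adjusted p of 0.00187, and adjusted p = 0.463 with an estimated correlation. Serine synthesis and ATF4 response genes were lower in 13 of 25 cases and higher in 4 (13 and 4 adjusted over the list alone; median -0.32), with ATF4 at -1.45, the glycyl tRNA synthetase GARS at -0.73 and the secreted STC2, below the filter in U937, at 1.31. The list had an adjusted p of 0.00562, and adjusted p = 0.188 with an estimated correlation.

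The OTX change of interferon response genes was higher in U937 in 14 of 23 cases and lower in 3 (14 and 3 adjusted over the list alone). The median log2 difference was 0.46, with the antiviral genes RSAD2 at 1.35 and OAS1 at 1.23. RSAD2 lay below the filter in U937. For this list camera gave an adjusted p of 0.00604, and adjusted p = 0.188 with an estimated correlation. Inflammatory genes were lower in 11 of 21 cases and higher in 4 (11 and 4 adjusted over the list alone; median -0.49), with the NF-kB genes TNFAIP3 at -1.26 and NFKB2 at -1.30 against TNFAIP2 at 2.40. Camera put their adjusted p at 0.0169, and adjusted p = 0.228 with an estimated correlation. Lymphoid markers differed upward in 6 of 9 cases and downward in 2 (6 and 2 adjusted over the list alone; median 0.74). LCK (2.39) and CD79B (2.69) lay below the filter in U937, so these values restate their fall in IMS-M2 (-2.41 and -2.66). The 5 members measured in U937 had a median change of -0.57 there. In camera the adjusted p was 0.0169, and adjusted p = 0.25 with an estimated correlation. All 4 stromal and epithelial markers differed upward (4 adjusted over the list alone; median 1.07). CDH5 (1.81), KRT8 (0.47) and KRT18 (0.36) lay below the filter in U937 and restate their fall in IMS-M2, and PECAM1 (1.67) fell in both lines (-2.24 and -0.57). The list is therefore no evidence of a rise in U937. Their adjusted p was 0.00422, and adjusted p = 0.173 with an estimated correlation. Genes reported as raised by BET inhibitors were lower in 5 of 11 cases (5 adjusted over the list alone; median -0.24). The list had an adjusted p of 0.0389, and adjusted p = 0.461 with an estimated correlation. The other lists were not called.

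The comparison that the series title names asked whether the OTX change depended on folic acid, as the -FA change minus the +FA change, which use separate DMSO libraries. In this comparison, higher and lower refer to that difference of changes, not to levels. In IMS-M2, CHAC1, a glutathione-degrading enzyme induced by ATF4, went from 6.47 ± 0.514 to 4.26 ± 0.648 FPKM under OTX with folic acid and from 5.02 ± 0.458 to 16.5 ± 1.56 FPKM without it (mean ± SD, n = 3 per group). The stress gene DDIT4, an inhibitor of mTOR, went from 18.5 ± 0.622 to 25.8 ± 4.30 FPKM with folic acid and from 13.1 ± 0.370 to 68.9 ± 11.1 FPKM without it. PCK2, a mitochondrial enzyme of the amino acid response, fell from 40.6 ± 1.51 to 17.5 ± 2.73 FPKM with folic acid and stood at 35.7 ± 2.36 and 46.7 ± 3.75 FPKM without it. ASNS, asparagine synthetase, went from 48.9 ± 9.85 to 72.8 ± 3.16 FPKM with folic acid and from 46.7 ± 1.47 to 170 ± 6.54 FPKM without it. The differences were 2.05 ± 0.15 (SE) on the log2 scale for CHAC1, 1.85 ± 0.17 for DDIT4, 1.55 ± 0.15 for PCK2 and 1.26 ± 0.17 for ASNS, which is named by its change without folic acid. Their limma adjusted p-values were 4.94e-05, 0.0003, 0.000395 and 0.00332.

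**Figure D3:**
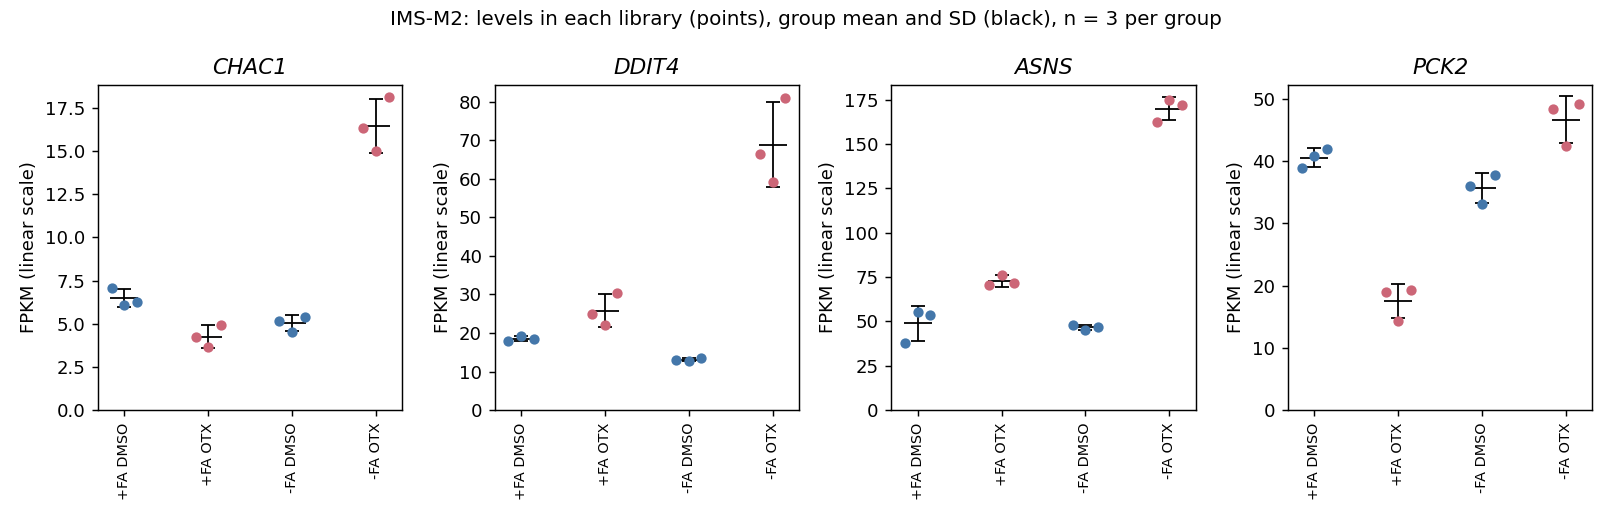
FPKM (linear scale) of CHAC1, DDIT4, ASNS and PCK2 in the 12 IMS-M2 libraries, by group, with DMSO in blue, OTX in red and the group mean and SD in black (n = 3). The 3 -FA OTX libraries lay between 15.0 and 18.1 FPKM for CHAC1 and between 163 and 175 FPKM for ASNS, above the other 9 libraries.

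CD53 fell less under OTX without folic acid in IMS-M2 (log2 difference 1.49), from 31.4 ± 3.02 to 13.3 ± 1.84 FPKM against 39.8 ± 10.01 to 5.30 ± 0.723 FPKM with it. FAM45A (1.59) lost its call in 6 of 12 omissions of a library (adjusted p from 0.0543 to 0.073), and SNORA48 was listed at 0 under OTX with folic acid. SNORA48 lost its call without +FA OTX replicate 2 (adjusted p = 0.0517), -FA OTX replicate 1 (0.0608) or -FA OTX replicate 3 (0.0507). The 6 lowest differences were RPS25 (-1.69), EMC6 (-1.61), GNG10 (-1.45), MRPL54 (-1.43), DNAAF3 (-1.41) and RPL24 (-1.37). In these 6 the +FA DMSO libraries scattered, as in RPS25, a ribosomal protein, at 598 ± 400 FPKM. Each lost its call in 7 to 10 of the 12 omissions of a library (adjusted p up to 0.126), and all kept it without +FA DMSO replicate 1 or -FA OTX replicate 2. BCL2 differed by -0.66 (adjusted p = 0.0249), a call lost without +FA OTX replicate 1 (0.0568) or 2 (0.0609), -FA DMSO replicate 2 (0.0656) or 3 (0.0512), or -FA OTX replicate 1 (0.081) or 3 (0.0647). MYC (-0.15, adjusted p = 0.304), HEXIM1 (-0.28), SERPINI1 (-0.01), BRD2 (0.19) and CDK6 (-0.01) did not pass. HEXIM1 passed without +FA DMSO replicate 1 (log2 -0.38, adjusted p = 0.0183).

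In limma, 779 of 11223 genes differed with folic acid in IMS-M2, 374 higher and 405 lower, with 80 by a log2 of at least 1 (33 higher and 47 lower). The count depended on single libraries. It was 3429 without +FA DMSO replicate 1, 235 without +FA DMSO replicate 2 and 198 without +FA DMSO replicate 3. It was 202, 160 and 260 without +FA OTX replicates 1, 2 and 3. It was 153, 146 and 298 without -FA DMSO replicates 1, 2 and 3, and 82, 1252 and 127 without -FA OTX replicates 1, 2 and 3. CHAC1, DDIT4, PCK2 and CD53 kept their calls in each of these 12 omissions, and ASNS was not refitted in them.

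**Figure D4:**
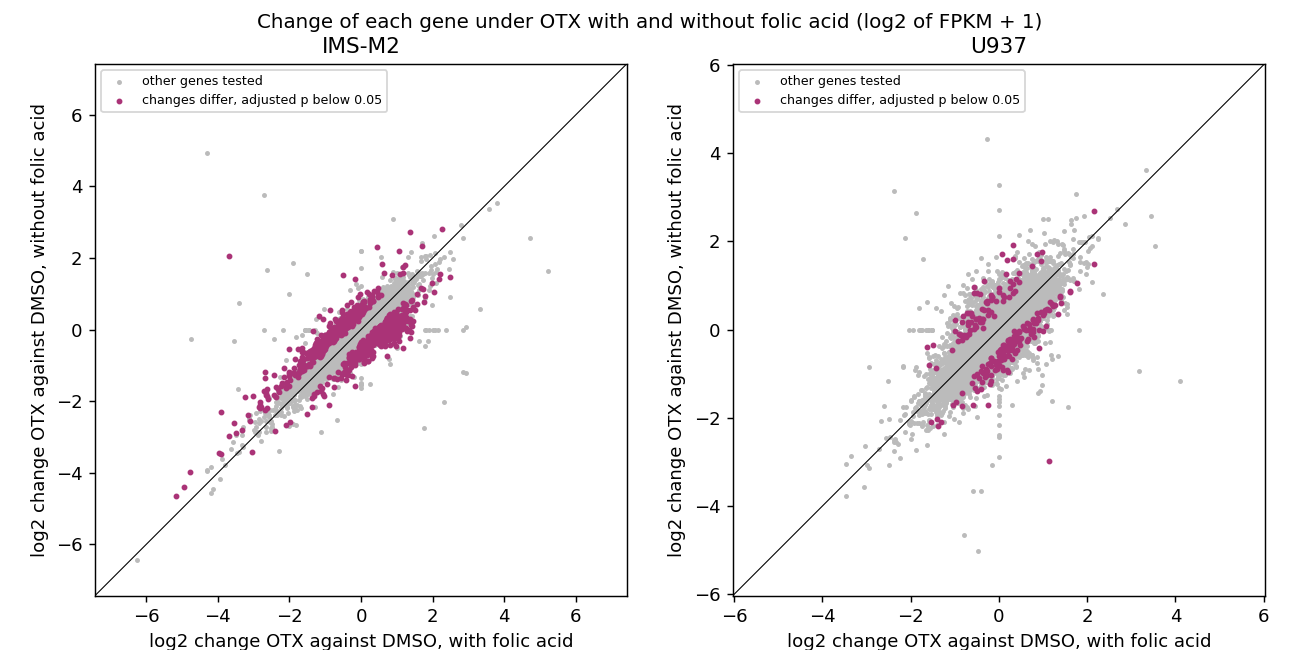
Log2 change under OTX with folic acid (x axis) and without it (y axis) for the tested genes of IMS-M2 and U937, each point 1 gene, with the diagonal as a line. Purple points are the 779 genes in IMS-M2 and 225 in U937 whose change differed with folic acid, and grey points are the others.

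Serine synthesis and ATF4 response genes differed as a list in IMS-M2, with 14 of 25 higher and 1 lower (16 and 1 adjusted over the list alone; median log2 difference 0.57). SLC7A11, a cystine transporter, was higher by 0.93, and CEBPB, a transcription factor, lower by 0.76, a call that CEBPB kept only without +FA DMSO replicate 1, -FA DMSO replicate 3 or -FA OTX replicate 2 (0.0582 to 0.105 otherwise). The camera adjusted p was 1.12e-09, and adjusted p = 0.122 with an estimated correlation. Mitosis genes were lower in 8 of 30 cases (15 adjusted over the list alone; median -0.33), with HMMR at -0.98 and the survival factor BIRC5 at -0.68. HMMR and BIRC5 kept their calls only without +FA DMSO replicate 1 or -FA OTX replicate 2 (adjusted p from 0.0509 to 0.0985 otherwise). The mitosis count was 14 lower and 3 higher without +FA DMSO replicate 1, 12 without -FA OTX replicate 2, and 0 or 1 without any other library. The adjusted p of the list was 7.88e-06, and adjusted p = 0.303 with an estimated correlation. S phase genes were lower in 2 of 30 cases (2 adjusted over the list alone; median -0.16), the replication factor GINS2 (-0.57) and the chromatin assembly factor CHAF1B (-0.55). CHAF1B kept its call only without the same 2 libraries (0.0568 to 0.109 otherwise), and GINS2 lost it without -FA OTX replicate 1 (0.0642) or 3 (0.0507). The S phase count was 6 lower and 2 higher without +FA DMSO replicate 1, 5 without -FA OTX replicate 2, 0 without -FA OTX replicate 1 or 3, and 1 otherwise. For this list camera gave an adjusted p of 0.00247, and adjusted p = 0.351 with an estimated correlation.

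Among the genes named next, ITGAM, HSPB1, HSPH1 and TM7SF2 lost their calls in 3, 1, 10 and 7 of the 12 omissions of a library (adjusted p up to 0.123). MRC1 and RSAD2 kept theirs. The counts of the 4 lists below rested on single libraries as well. Without +FA DMSO replicate 1 they were 6 for monocyte markers, 7 higher and 1 lower for interferon, 4 lower and 1 higher for heat shock, and 11 higher and 4 lower for cholesterol synthesis. Without -FA OTX replicate 2 they were 4, 4, 2 and 5 in that order. Without any other library they were 1 or 2, except heat shock at 1, or 0 without -FA OTX replicate 1. The OTX change of monocyte markers was higher without folic acid in IMS-M2 in 3 of 9 cases (5 adjusted over the list alone). The list had a median log2 difference of 0.30, and the mannose receptor MRC1 (0.62) and the integrin ITGAM (0.64) were among the 3. Under OTX the list fell in both conditions (medians -1.15 with and -0.95 without folic acid). In DMSO its median without minus with folic acid was -0.37, with 2 of 9 members higher, so the difference need not arise under OTX. Camera put the adjusted p of the list at 0.00272, and adjusted p = 0.155 with an estimated correlation. Interferon response genes were higher in 3 of 17 cases (9 and 1 lower adjusted over the list alone; median 0.29), with RSAD2 at 0.85. In camera the adjusted p was 0.00247, and adjusted p = 0.136 with an estimated correlation. Heat shock genes were lower in 2 of 13 cases (2 adjusted over the list alone; median -0.23), the chaperones HSPB1 (-0.71) and HSPH1 (-0.62). Tested with camera, they had an adjusted p of 0.00684, and adjusted p = 0.136 with an estimated correlation or 0.0715 without +FA DMSO replicate 1. Cholesterol synthesis genes were higher in 3 of 23 cases (7 and 1 lower adjusted over the list alone; median 0.25), with the sterol reductase TM7SF2 at 0.68. The list had an adjusted p of 0.0401, and adjusted p = 0.169 with an estimated correlation. That call was also lost without +FA DMSO replicate 1 (0.11) or 2 (0.0504), +FA OTX replicate 3 (0.076), -FA DMSO replicate 3 (0.0625) or -FA OTX replicate 3 (0.0561).

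In U937 the same question gave fewer called genes (225, against 779 in IMS-M2). More genes had an unadjusted limma p under 0.05 there (3791, against 3381 in IMS-M2). The smaller count therefore does not show a weaker dependence on folic acid. MCM2, a subunit of the replicative helicase, stood at 132 ± 19.99 and 116 ± 7.01 FPKM in DMSO and OTX with folic acid, and at 158 ± 21.1 and 69.4 ± 8.09 FPKM without it (mean ± SD, n = 3 per group). UHRF1, which keeps DNA methylation through replication, stood at 59.3 ± 3.28 and 67.0 ± 5.49 FPKM with folic acid and at 65.5 ± 1.43 and 43.0 ± 3.42 FPKM without it. IFIT2 stood at 0.257 ± 0.0433 and 1.29 ± 0.128 FPKM with folic acid and at 0.313 ± 0.0238 and 3.35 ± 0.457 FPKM without it. FADS1, a fatty acid desaturase, rose from 51.3 ± 2.74 to 104 ± 1.99 FPKM only with folic acid and stood at 43.9 ± 1.87 and 43.1 ± 2.42 FPKM without it. The log2 differences were -1.0 ± 0.19 (SE) for MCM2, -0.77 ± 0.12 for UHRF1, 0.86 ± 0.12 for IFIT2 and -1.03 for FADS1. Their limma adjusted p-values were 0.0454, 0.0379, 0.0379 and 0.0059.

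Other leading differences in U937 were DLX2, a homeobox gene (1.63), the antisense RNA HIF1A-AS2 (1.59), SELM (1.44), the splicing factor SNRNP27 (1.40), NDUFC2 (1.38) and LAIR2 (1.33). On the lower side stood SCARNA12 (-1.47), PCNA-AS1 (-1.32), the helicase subunit MCM5 (-1.16), haptoglobin, HP (-1.13), and BLVRB, a haem breakdown enzyme (-1.10). CD180 differed by -0.79 on this scale, but by -0.47 (adjusted p = 0.241) with a pseudocount of 0.1 FPKM and -0.19 (0.69) with 0.01, so its call depended on the pseudocount. Each of these genes lost its call in 9 or 10 of the 12 omissions of a library (adjusted p from 0.0517 to 0.148), and all kept it without +FA DMSO replicate 1 or -FA DMSO column 1. MYC (-0.10, adjusted p = 0.611), HEXIM1 (0.78, 0.081), SERPINI1 (0.84, 0.0525), BCL2 (-0.06), BRD2 (-0.14) and CDK6 (-0.44) did not pass. HEXIM1 passed without -FA DMSO column 1 (0.029). SERPINI1 passed without that library (0.0209) or without +FA DMSO replicate 1 (0.0342).

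In limma, 225 of 11194 genes differed with folic acid in U937, 83 higher and 142 lower, with 29 by a log2 of at least 1 (18 higher and 11 lower), and 3791 had an unadjusted p under 0.05. The count rested on every library. It was 2184, 1 and 2 without +FA DMSO replicates 1, 2 and 3, and 2, 1 and 2 without +FA OTX replicates 1, 2 and 3. It was 1, 2704 and 1 without -FA DMSO columns 0, 1 and 2, and 79, 2 and 2 without -FA OTX columns 0, 1 and 2. MCM2, UHRF1 and IFIT2 kept their calls only without +FA DMSO replicate 1, -FA DMSO column 1 or -FA OTX column 0 (adjusted p up to 0.146, 0.131 and 0.117 otherwise), and FADS1 kept its call in all 12 omissions.

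**Figure D5:**
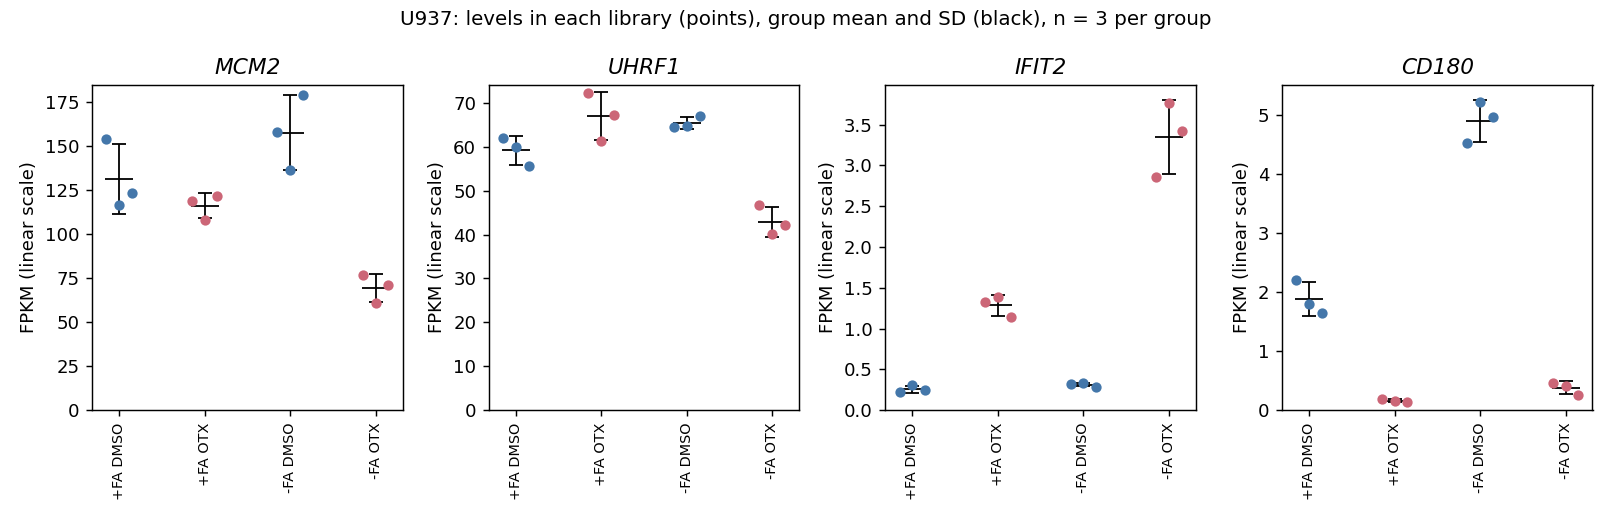
FPKM (linear scale) of MCM2, UHRF1, IFIT2 and CD180 in the 12 U937 libraries, by group, with DMSO in blue, OTX in red and the group mean and SD in black (n = 3). The 3 -FA OTX libraries lay between 60.7 and 76.7 FPKM for MCM2 and between 40.1 and 46.8 FPKM for UHRF1, below the other 9 libraries of each gene.

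The OTX change of S phase genes was lower without folic acid in U937 in 4 of 30 cases (16 adjusted over the list alone). The median log2 difference was -0.39, and FEN1, a flap nuclease (-0.69), was among the 4. The count was 15 without +FA DMSO replicate 1 or -FA DMSO column 1, 2 without -FA OTX column 0, and 0 otherwise. Their camera adjusted p was 1.06e-05, and adjusted p = 0.239 with an estimated correlation. Interferon response genes were higher in 4 of 21 cases (8 adjusted over the list alone; median 0.24), with XAF1, a promoter of cell death, at 0.60 and IFIT3 at 0.59. Without the same 3 libraries the count was 6, 7 and 2, and it was 0 otherwise. Their adjusted p was 0.000223, and adjusted p = 0.239 with an estimated correlation. Genes reported as raised by BET inhibitors had 0 of 11 called (4 higher adjusted over the list alone; 3 and 5 called without +FA DMSO replicate 1 and -FA DMSO column 1) and a median of 0.54. By camera, the adjusted p was 0.00108, and adjusted p = 0.344 with an estimated correlation. Methylation enzymes had 0 of 28 called (11 lower and 1 higher adjusted over the list alone; 8 and 9 lower and 1 higher without the same 2 libraries) and a median of -0.21. With camera, the adjusted p was 0.00748, and adjusted p = 0.286 with an estimated correlation. In genes reported as lowered the OTX change was lower in 3 of 10 cases (4 adjusted over the list alone, median -0.31). These were CD180, CSF1R (-0.52) and the chemokine receptor CCR2 (-0.50). The level of CD180 was higher without folic acid in both DMSO (4.90 against 1.89 FPKM) and OTX (0.376 against 0.156 FPKM). CCR2 changed sign with a pseudocount of 0.01 FPKM (log2 0.28). The count was 4 without +FA DMSO replicate 1, 3 without -FA DMSO column 1, 1 without -FA OTX column 0, and 0 otherwise. FEN1 (0.0517 to 0.146), XAF1 (0.0517 to 0.137) and CSF1R (0.0543 to 0.146) kept their calls only without +FA DMSO replicate 1 or -FA DMSO column 1. CCR2 (0.0543 to 0.146) did so too, and lay below the filter without -FA DMSO column 2. IFIT3 (0.0658 to 0.146) and CD180 (0.0567 to 0.131) also kept theirs without -FA OTX column 0. The genes reported as lowered had an adjusted p of 0.0364, and adjusted p = 0.239 with an estimated correlation. That call was also lost without +FA DMSO replicate 1 (0.0899), +FA OTX replicate 2 (0.055), -FA DMSO column 1 (0.0657) or column 2 (0.1). Serine synthesis and ATF4 response genes were not called in U937 (median -0.08, adjusted p = 0.467). Their mean (0.02) and the test pointed up, so they had no clear direction. The remaining lists were not called either.

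Across genes, which are not independent replicates, the OTX changes with and without folic acid correlated at a Pearson r of 0.82 and a Spearman rho of 0.79 in IMS-M2. In U937 these were 0.74 and 0.71. Single libraries moved r, from 0.77 without +FA DMSO replicate 1 to 0.86 without +FA DMSO replicate 3 in IMS-M2, and from 0.66 without +FA DMSO replicate 1 to 0.80 without -FA DMSO column 2 in U937. With a pseudocount of 0.01 FPKM r was 0.80 and 0.68. Of 4947 genes called in both conditions in IMS-M2, 61 moved in opposite directions, as did 61 of 4516 in U937. Between the lines r was 0.40 with folic acid, where 676 of 3739 genes called in both moved in opposite directions, and 0.52 without it, where 426 of 3841 did. In IMS-M2, 2215 genes rose in both conditions against 918 by chance, and 2671 fell against 1126. In U937, 2133 rose in both against 914, and 2322 fell against 959.

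Levels in DMSO without and with folic acid come from separate tables and were not tested. In IMS-M2, AMT, a glycine cleavage enzyme, stood at 1.68 ± 0.493 FPKM without and 4.31 ± 1.52 FPKM with folic acid (mean ± SD, n = 3 per group). MAT2A, which makes S-adenosylmethionine, stood at 158 ± 7.61 and 235 ± 52.0 FPKM, AHCY, which clears its product, at 195 ± 17.7 and 250 ± 32.2 FPKM, and PEMT at 30.1 ± 1.01 and 38.7 ± 4.98 FPKM. The 3 libraries of each group lay apart for these 4 genes. In U937, MAT2A stood at 162 ± 41.8 FPKM without and 121 ± 33.7 FPKM with folic acid, and AMT at 3.63 ± 1.33 and 2.71 ± 0.694 FPKM, and for both the libraries of the 2 groups overlapped. The folate carrier SLC19A1 stood at 66.1 ± 11.1 and 51.3 ± 1.46 FPKM and the serine hydroxymethyltransferase SHMT2 at 167 ± 8.80 and 203 ± 15.2 FPKM, and for both the groups lay apart. The ratio without to with folic acid was 0.927 in IMS-M2 and 0.907 in U937 for MYC.

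On build hg19 the tables place MYC on chromosome 8 at 128748314 to 128753680, HEXIM1 on chromosome 17 at 43224683 to 43229468, and SERPINI1 on chromosome 3 at 167453431 to 167543357. They place IGLL1 on chromosome 22 at 23915312 to 23922495, CHAC1 on chromosome 15 at 41245635 to 41248717, and DDIT4 on chromosome 10 at 74033676 to 74035797. They place ASNS on chromosome 7 at 97481428 to 97501854, PCK2 on chromosome 14 at 24563482 to 24573339, and CDKN1A on chromosome 6 at 36644236 to 36655116. MCM2 lies on chromosome 3 at 127317199 to 127341278 and IFIT2 on chromosome 10 at 91061705 to 91069033. UHRF1 (chromosome 19, 4909509 to 4962165) shares its locus with another gene.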

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

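The tests of single libraries, transcript length, DMSO shifts, drug action, scaling and exchanged labels were chosen only after the results were seen, and the regroupings of libraries were set before.

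In IMS-M2 the OTX change of the serine synthesis and ATF4 response list was higher without folic acid (median log2 difference 0.57). The list median was 0.32 without folic acid and -0.26 with it, where the list was not called. The difference was led by CHAC1 (2.05), DDIT4 (1.85), PCK2 (1.55), ASNS (1.26) and SLC7A11 (0.93). Only 1 of 100 regroupings gave a median as far from 0, the real one, with 0.44 the highest other, which speaks against chance. The median difference stayed at 0.51 or above without any single library (highest camera adjusted p 1.4e-06) and was 0.59 with the length trend removed (4.61e-10). In DMSO the list median without minus with folic acid was -0.047 against 0.61 under OTX, with 12 and 24 of 25 members higher. A shift of the DMSO libraries would thus not produce the list median, though these levels come from separate tables. CHAC1 (5.02 against 6.47 FPKM) and DDIT4 (13.1 against 18.5 FPKM) were lower in DMSO without folic acid, so part of their differences lay there. The call was lost with an estimated correlation (0.122). An amino acid or folate stress that OTX unmasks may explain the list, a hypothesis that was not tested here. The folate and methionine cycle list did not pass in the same comparison (median 0.04, adjusted p = 0.458), and no protein or metabolite was measured. Measuring amino acids and folates under OTX, and adding them back, would decide it.

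MYC fell further in U937 than in IMS-M2 (-2.51). A weaker action of the drug in IMS-M2 might explain that, but with folic acid, where the lines were compared, HEXIM1 rose more in IMS-M2 (difference -1.06, adjusted p = 0.000505). SERPINI1 did not pass there (0.09, adjusted p = 0.723). Without folic acid the lines were not compared by a test. HEXIM1 rose by 2.03 in IMS-M2 and 2.02 in U937, SERPINI1 by 1.06 and 2.0, BRD2 by 1.01 and 0.44, and the median of the genes reported as raised was 1.86 and 1.63. MYC fell by 0.62 and 3.08. Of these readouts only SERPINI1 rose less in IMS-M2, and without a test a weaker action there was not settled. HEXIM1 and SERPINI1 are also members of the list of genes reported as raised, so these readouts overlap. Library scaling left the MYC difference at -2.46 or further from 0. A difference between the lines in how MYC depends on BET proteins could explain it and was not tested. The labels give no dose or duration of OTX, so whether both lines were treated alike is unknown. In regroupings 1 of 100 called as many genes as the real 6175. The highest other, 3433, exchanged only 1 DMSO library between the lines.

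The folic acid difference called 779 genes in IMS-M2 and 225 in U937. In regroupings 2 of 100 called at least as many in IMS-M2 and 2 of 100 in U937, the real one among them. In IMS-M2 the highest other was 1940 and exchanged only +FA DMSO replicate 1 and -FA DMSO replicate 3. In U937 it was 3747 and exchanged only +FA DMSO replicate 1 and -FA DMSO column 1. Both lie well above the real count, which points to a structure of the samples other than the labels, and its source was examined in U937 alone. Exchanged labels might explain it there, but monocyte markers placed both libraries with their labels (replicate 1 at -0.04, and a gap of 0.42 between the groups). Of the lists measured, that list differed most between these DMSO groups by the same labels (median 0.75), and the groups come from separate tables. Its separation was thus partly given in advance. In the DMSO libraries not in question, its median was -0.12 and -0.23 in +FA replicates 2 and 3. It was 0.45 and 0.38 in -FA columns 0 and 2. Replicate 1 (-0.04) and column 1 (0.49) each lay with their own label. For mitosis genes, replicate 1 lay at -0.10 beside 0.07 and -0.06, and column 1 at -0.32 beside -0.34 and -0.52. These values argue against exchanged labels of these 2 libraries. A length trend could explain the structure, but with that trend removed the exchange called 3019 genes against 258 by the labels. As deposited, in the same form of fit, it called 3171 against 225.

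For OTX against DMSO only 10 regroupings exist per table, too few to pass a share of 0.05. Of these 10, 1 called as many genes in each table, the real one. The real counts and highest others were 7091 and 1 in IMS-M2 with folic acid, 6455 and 1 without it, 6281 and 2 in U937 with folic acid, and 6690 and 1 without it.

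Other list medians of the folic acid difference in IMS-M2 were -0.16 for S phase, -0.33 for mitosis, 0.30 for monocyte markers, 0.25 for cholesterol synthesis, 0.29 for interferon response and -0.23 for heat shock. Other genes there were SNORA48 (5.75), FAM45A (1.59), CD53 (1.49), RPS25 (-1.69), EMC6 (-1.61), GNG10 (-1.45), MRPL54 (-1.43), DNAAF3 (-1.41), RPL24 (-1.37) and BCL2 (-0.66). List members there were CEBPB (-0.76), GINS2 (-0.57), CHAF1B (-0.55), HMMR (-0.98), BIRC5 (-0.68), MRC1 (0.62), ITGAM (0.64), TM7SF2 (0.68), RSAD2 (0.85), HSPB1 (-0.71) and HSPH1 (-0.62).

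In U937 the list medians of the folic acid difference were 0.54 for genes reported as raised by BET inhibitors, -0.31 for those reported as lowered, -0.39 for S phase, -0.21 for methylation enzymes and 0.24 for interferon response. Genes there were DLX2 (1.63), HIF1A-AS2 (1.59), SELM (1.44), SNRNP27 (1.40), NDUFC2 (1.38), LAIR2 (1.33), SCARNA12 (-1.47), PCNA-AS1 (-1.32), MCM5 (-1.16), HP (-1.13), BLVRB (-1.10) and FADS1 (-1.03). List members there were UHRF1 (-0.77), MCM2 (-1.0), FEN1 (-0.69), IFIT2 (0.86), XAF1 (0.60), IFIT3 (0.59), CD180 (-0.79), CSF1R (-0.52) and CCR2 (-0.50).

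Between the lines the list medians were -0.24 for genes reported as raised by BET inhibitors, -0.56 for MYC targets, -0.32 for the ATF4 list and 0.46 for interferon response. They were -0.49 for inflammatory genes, 0.74 for lymphoid markers, 1.07 for stromal markers, -0.48 for histone genes and -0.26 for ribosomal proteins. Upward stromal members mostly lay below the filter in U937, as did the lymphoid LCK and CD79B, so these restate their fall in IMS-M2. Leading genes were CCL1 (5.15), IGLL1 (4.76), SLC38A5 (4.56), SELP (4.30), CD53 (4.20), ANGPT1 (4.13), SNORA44 (-6.93), SNORA33 (-4.73), BCYRN1 (-3.74), SNORA6 (-3.61), SNORA81 (-3.43) and MS4A3 (-3.42). CD180 stood at -1.27 and BCL2 at -0.42. List members were NOLC1 (-1.10), NPM1 (-1.03), SLC29A2 (1.19), ATF4 (-1.45), GARS (-0.73), STC2 (1.31), RSAD2 (1.35), OAS1 (1.23), LCK (2.39) and CD79B (2.69). Others were HIST2H2BE (-1.73), HIST1H1B (-1.25), RPL4 (-0.69), RPL12 (-0.75), TNFAIP3 (-1.26), NFKB2 (-1.30), TNFAIP2 (2.40), PECAM1 (1.67) and CDH5 (1.81).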

How the results depend on the processing

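Removing the length trend, leaving out small RNA symbols and testing lists without each library were chosen only after the results were seen.

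The counts of genes changed by OTX with a log2 change of at least 1 moved with the pseudocount. With 0.01 FPKM the count was 1811 in IMS-M2 with folic acid. With 0.1 and 0.01 FPKM it was 1380 and 1456 in IMS-M2 without folic acid, 1394 and 1484 in U937 with it, and 1637 and 1707 in U937 without it. The line difference moved to 2120 and 2190. A smaller pseudocount raises the change of low genes.

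The folic acid difference moved most. In IMS-M2 it was 445 genes (29 at a log2 of at least 1) with no filter on low values, 1920 with a replicate block and 5527 (176) with array weights, and at a log2 of at least 1 it was 150 and 169 with pseudocounts of 0.1 and 0.01 FPKM. In U937 it was 31 (7) and 31 (9) with those pseudocounts, 128 (7) with no filter, 6302 (276) with array weights and 541 (60) without small RNA symbols. The fit of array weights stopped before convergence in U937, so its counts there carry little weight. The cause was not tested. Leaving out 1 library gave 82 to 3429 genes in IMS-M2, 18 to 220 at a log2 of at least 1, lowest without -FA OTX replicate 1 and highest without +FA DMSO replicate 1. In U937 it gave 1 to 2704, and 0 to 393 at a log2 of at least 1, lowest without +FA DMSO replicate 2 and highest without -FA DMSO column 1. Reading the folic acid difference as a count of genes is therefore not safe in either line.

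Leaving out 1 library gave 6444 to 7471 genes changed by OTX in IMS-M2 with folic acid, 5680 to 5987 without it, 5449 to 6106 in U937 with folic acid, 5650 to 6693 without it, and 5312 to 6581 for the line difference.

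With a pseudocount of 0.01 FPKM, 3 named results changed sign and lost their call. They were CCR2 in the U937 folic acid difference (0.28, adjusted p = 0.834) and MX2 (0.16, 0.308) and KRT8 (-0.15, 0.878) in the line difference. MX2 lay below the filter in IMS-M2 and KRT8 in U937. Of the other named results 363 stayed and 27 weakened. With 0.1 FPKM 366 stayed and 27 weakened, with no filter 358 stayed and 35 weakened, with rescaling 390 stayed and 2 weakened, and with quantile normalization 385 stayed and 7 weakened.

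With an estimated correlation 4 of 42 list calls under OTX held, histone genes in IMS-M2 with and without folic acid and MYC targets and the ATF4 list in U937 with folic acid. With the length trend removed 163 list results stayed and 2 lost their call, p53 targets in IMS-M2 with folic acid and BET proteins and elongation genes in IMS-M2 without it (adjusted p = 0.06 for both).

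The library numbers were not taken to pair samples, since not every pair correlated above 0.1. DMSO and OTX deviations of equal number correlated at 0.0521, 0.28 and 0.0741 in IMS-M2 with folic acid, 0.08, 0.21 and 0.19 without it, and -0.34, 0.13 and -0.24 in U937 with folic acid. The highest with another number was 0.034, -0.14 and 0.0683, then -0.03, -0.10 and 0.01, then 0.50, 0.22 and 0.16. So all 6 IMS-M2 DMSO libraries and 0 of 3 in U937 correlated best with their own number, a hint from the data, not the design. With a replicate block the counts were 7655 in IMS-M2 with folic acid, 7083 without it, 5865 in U937 with it, 1920 for the folic acid difference in IMS-M2 against 779, and 6017 between the lines. No paired analysis was possible because the columns of U937 without folic acid, numbered from 0, cannot be matched to the labelled replicates, so they carry no replicate number. This holds for OTX there and for the folic acid difference in U937. The depth of the libraries is unknown, so how far counting noise limits low genes cannot be said.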

Other observations

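No test was chosen after the result for this part. MIR1282, a micro RNA gene, stood at 7613 FPKM in IMS-M2 +FA DMSO replicate 3, 28869 in IMS-M2 -FA OTX replicate 2, 22862 in U937 +FA DMSO replicate 3 and 10601 in U937 +FA OTX replicate 2, and was listed at 0 in the other 20 libraries. HBB, a haemoglobin gene, stood at 10.4 FPKM in IMS-M2 -FA OTX replicate 2, while HBA1 and HBA2 were listed at 0 there.

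Ribosomal protein genes made up 26.04% to 28.3% of FPKM in the 6 IMS-M2 DMSO libraries and 24.1% to 26.2% in the 6 with OTX. In U937 they made up 20.8% to 23.3% in DMSO and 15.4% to 17.9% with OTX. In U937 DMSO libraries, which were not tested across tables, 18 of 19 monocyte markers were higher without folic acid (median log2 0.75), 14 of 15 inflammatory genes were higher (0.44), and 0 of 30 mitosis genes were (-0.34). In IMS-M2 DMSO libraries 18 of 23 cholesterol synthesis genes were higher without folic acid (0.34).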
